A study of Mus musculus with 12 samples.

How the data were processed

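RNA was measured by sequencing in 12 libraries of mouse spleen CD8+ T cells, in 4 groups of 3: WT and CKO cells at 0 h and at 48 h of stimulation. Per the labels' protocols, RNA was extracted with TRIzol and libraries were made with a TruSeq Stranded mRNA kit. The deposited values are raw counts per Ensembl gene, whole numbers that were neither scaled nor logged. Per the submitters' processing notes, cutadapt, HISAT2 2.2.1, DESeq2 and the genome build GRCm39 were used, with no role or order given. The counting program, the annotation release, the strand setting and any read filter are not given in the sources used here. Reads of a gene and its antisense partner, or of near-identical copies, could therefore have been counted at either.

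The table held 56691 gene IDs, of which 30285 had at least 1 count in any library. Symbols were taken from a reference name table by ID for 52073 of them, and the IDs without a symbol held 0.249% of all counts. Positions were looked up by ID in an annotation of GRCm38, since none of GRCm39 was at hand, and were used only to tell which genes lie near each other. Library totals ran from 15900529 to 22427151 counts. Intervals and floors below cover counting error only.

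Counts were scaled with TMM factors and fitted with edgeR 4.0.16 (quasi-likelihood, robust, model with 1 mean per group) in R 4.3.3. All 12 libraries entered one fit, which left 8 residual degrees of freedom. Genes kept by filterByExpr on the 4 groups, 15935 in all, were tested. The p-values are two-sided and adjusted by the Benjamini-Hochberg method over these genes, and "edgeR adjusted p" below means this test. A gene was called at an adjusted p under 0.05. The 5 contrasts were 48 h against 0 h in WT and in CKO, CKO against WT at 0 h and at 48 h, and the difference between the responses of CKO and WT (the interaction). Levels are given as CPM, counts scaled to a common total, on TMM-scaled totals with the SD, and log2 changes with their standard error (SE). The labels do not say that the replicates came from separate animals, so p-values measure the spread between these samples. Their common biological coefficient of variation was 0.0999.

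The tests, alternatives, gene lists and naming rule were fixed before the data were examined, apart from the additions named here and in the closing part. There were 36 lists with 785 distinct members, of which 771 were matched to an ID, 24 of them through an older symbol. The lists covered the SUMO pathway, naive and quiescence genes, early activation, cytotoxic effector, memory, inhibitory receptor and T-cell receptor genes, and S-phase and G2/M genes. Others covered glycolysis, HIF-1 targets, oxidative phosphorylation, mitochondrial mRNAs, the TCA cycle, sirtuin and antioxidant genes, fatty acid oxidation, cholesterol synthesis, ATF4 targets, the unfolded protein response and ribosome biogenesis. Further lists held type I interferon, interferon gamma and MHC class I, p53, apoptosis, cytokine, cytokine receptor and STAT5 genes, and dissociation, histone and sex-linked genes. The remaining lists held markers of B cells, CD4 and regulatory T cells, natural killer and innate-like T cells, myeloid cells, neutrophils, and erythroid and platelet cells.

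Each list with at least 5 tested members was tested with camera (limma 3.58.1, preset correlation 0.01), adjusted over the lists of a contrast, with an estimated correlation and fry beside it. The naming rule took Senp1 and, per contrast and direction, the 8 protein-coding genes with the largest change. These had to have an adjusted p under 0.05, a mean CPM of at least 5 in the higher group and, except in the interaction, no overlap between libraries. It also took up to 4 members per list with the smallest adjusted p, or the 1 or 2 with the smallest p where none passed, and in the genotype contrasts 18 set genes whatever their result. Genes named outside this rule are said to be so, and 4 genes it named are not reported here. For genes with 3 counts or fewer in a group, folds were computed from summed counts with an exact 95% interval, and for groups at 0 as a lower bound against 3 counts over the group.

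Alternatives were median-of-ratios size factors, library totals only, no count filter, a stricter filter, a replicate block, thinning to the smallest library, fits of only the 2 groups compared, DESeq2 1.42.0, a log2 change of at least 1, and leaving out each library in turn. A replicate block within each genotype, and a fit without 2 WT libraries that stood apart (replicate 1 at each time), were added after seeing the data. Tables and figures were made with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9. No reads were used here.

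The tests were run on simulated counts with 200 changed genes per contrast. In the data 12409 genes were called for WT activation and 12377 for CKO activation. With more changed genes the Benjamini-Hochberg cut-off is looser, so the activation shares below do not measure sensitivity in the data. For a made log2 change of 0.5, 1 and 2, the share called was 32.8%, 65.7% and 90.9% for WT activation (15599 genes, 8 false calls) and 43.8%, 71.4% and 83.1% for CKO activation (15539 genes, 11 false calls). It was 50.8%, 68.7% and 90.8% for CKO against WT at 0 h (15504 genes, 19 false calls) and 43.9%, 72.7% and 89.2% at 48 h (15601 genes, 7 false calls). For the interaction it was 19.0%, 52.2% and 77.4% (15614 genes, 2 false calls). A single set was simulated per contrast. At 0 h the 19 false calls stood beside 33, 46 and 59 true ones, a false share above the 0.05 aimed at. It was also above 0.05 for CKO activation (11 beside 28, 45 and 54) and WT activation (8 beside 21, 44 and 60). At 48 h and in the interaction it was not.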

Results

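RNA was sequenced from mouse spleen CD8+ T cells that carried the Senp1 gene intact (WT) or deleted (CKO, the usual short form of conditional knockout). Senp1 encodes a protease that removes the small protein SUMO from its targets. The cells were naive and were left unstimulated (0 h) or stimulated for 48 h with antibodies to CD3 (5 µg/ml), part of the T-cell receptor complex, and to CD28 (1 µg/ml), a costimulatory receptor. Each of the 4 groups had 3 libraries, and totals ran from 15900529 to 22427151 counts. The first principal component held 83.4% of the variance and put the 0 h libraries between -107.8 and -100 and the 48 h libraries between 101.1 and 108. The second held 4.68% and put WT between 17.0 and 30.3 and CKO between -31.0 and -17.5. The series title asks what Senp1 does in the activation of these cells, so the responses of both genotypes and the genotypes at each time were compared.

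The targeted gene was examined first. Senp1 (ENSMUSG00000033075, chromosome 15 in GRCm38) was lower in every CKO library than in every WT library of the same time. At 0 h it stood at 82.4 ± 3.99 CPM in WT and 57.0 ± 2.64 CPM in CKO (SD, n = 3), so that CKO held 69.1% of the WT level (SE 2.68) and Senp1 fell by 0.53 ± 0.070 on the log2 scale (SE, edgeR adjusted p = 6.26e-05). At 48 h it stood at 161.7 ± 10.5 CPM in WT and 70.3 ± 4.13 CPM in CKO (SD, n = 3), or 43.5% of WT (SE 2.19, log2 change -1.20 ± 0.068, edgeR adjusted p = 5.43e-10). Senp1 rose with stimulation by 0.97 ± 0.068 (log2) in WT and by 0.30 ± 0.070 in CKO, and the responses differed by -0.67 ± 0.098 (edgeR adjusted p = 0.000926). The plot of Senp1 by library shows these values. Counts per gene cover all exons, and the exons removed are not given in the sources used here, so the share of cells with the deletion was not measured.

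**Figure D1:**
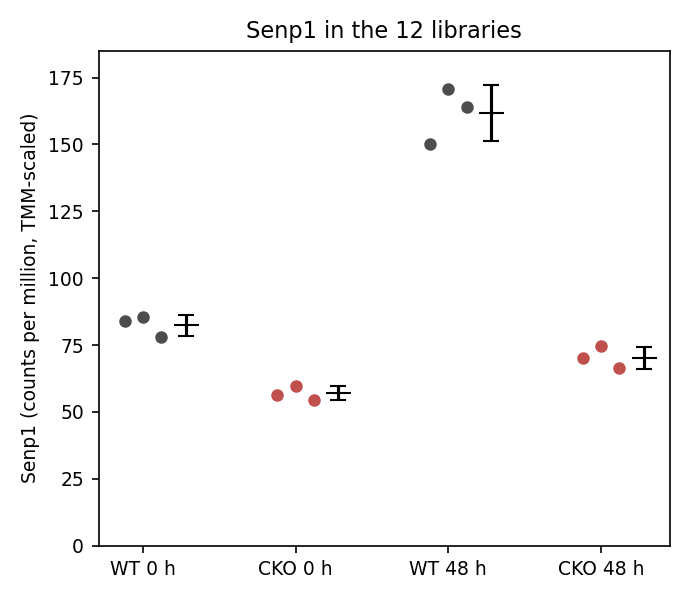
Senp1 level in CPM on TMM-scaled totals (vertical axis, from 0) for each of the 12 libraries, by genotype and time. Points are single libraries, and horizontal bars with whiskers give the mean and SD of 3 libraries. CKO means are 57.0 at 0 h and 70.3 at 48 h, against 82.4 and 161.7 in WT.

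The first comparison asked what 48 h of stimulation did in WT and in CKO cells. Genes of cell division, sugar breakdown and sterol synthesis rose, and genes of the resting naive state fell, in both genotypes. Il2, the T-cell growth factor, rose by 8.76 ± 0.976 (log2, SE, n = 3 per group, edgeR adjusted p = 3.68e-07) in WT and 8.44 ± 0.731 in CKO (edgeR adjusted p = 2.44e-07), and Il2ra, part of its receptor, by 7.45 ± 0.124 and 6.86 ± 0.119. S1pr1, which guides exit from lymphoid organs, fell by 6.90 ± 0.111 in WT, and Klf2, a transcription factor of resting T cells, fell by 6.58 ± 0.160 in WT and 6.87 ± 0.165 in CKO. In WT 6172 genes were higher and 6237 lower at 48 h of 15935 tested, and in CKO 6131 were higher and 6246 lower (edgeR). Of these, 5663 were higher in both genotypes and 5594 lower in both, against 2375 and 2445 if the calls were independent. Across genes, which are not independent replicates, the WT and CKO log2 changes had a Pearson r of 0.936, a Spearman rho of 0.954 and a slope of 0.993. With a log2 change of at least 1 added to the threshold, the counts were 3583 higher and 3955 lower in WT and 3560 higher and 3979 lower in CKO.

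The largest rises in WT included Tnip3, an inhibitor of NF-kB signalling (log2 change 9.11 ± 0.707), Psrc1, a spindle protein (8.89 ± 0.253), Serpine2, a protease inhibitor (8.39 ± 0.410), and Fads2, a fatty acid desaturase (8.27 ± 0.423), each with an edgeR adjusted p of 1.51e-10 or less. In CKO they included Serpine2 (9.01 ± 0.470) and Tnip3 (8.94 ± 0.893). Some of these genes were almost unread in one group. Robo3, an axon guidance receptor, was at least 132-fold higher at 48 h in WT and at least 96.1-fold in CKO, and Il3, a growth factor for blood cells, at least 70-fold and at least 192-fold. Zfp750 was 438-fold higher in WT (95% counting interval 121 to 3620) and at least 259-fold higher in CKO. Lrr1 was 585-fold higher in WT (162 to 4840), and in CKO Dnph1 was 417-fold (115 to 3440) and Idi2 413-fold higher (114 to 3420). The largest falls included Ccr9, a gut-homing chemokine receptor (-6.57 ± 0.254 in WT), Cd7 (-6.45 ± 0.326 in WT, -6.95 ± 0.367 in CKO), and in CKO Itgae, the integrin chain CD103 (-6.41 ± 0.190), Ggt1 (-6.53 ± 0.214) and Fosb (-6.75 ± 0.711). Cacna1i, a calcium channel, fell by 6.66 ± 0.685 in WT and was 180-fold lower in CKO (49.4 to 1490), and Lrrc23 was 236-fold lower in CKO (64.9 to 1950).

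Genes of the S and G2/M phases rose almost without exception. All 32 S-phase genes rose in both genotypes, with a median log2 change of 3.36 in each, among them Uhrf1, which keeps DNA methylation through replication (5.50 ± 0.086 in WT, 5.30 ± 0.085 in CKO), and Cdc45, a part of the replicative helicase (5.40 ± 0.108 and 5.06 ± 0.105). Of 30 G2/M genes 29 rose and 1 fell in both, with medians of 5.88 in WT and 5.14 in CKO, among them Birc5 (6.11 ± 0.143 and 5.64 ± 0.135) and Tpx2, a spindle assembly factor (6.80 ± 0.167 and 6.07 ± 0.143). All 30 ribosome biogenesis genes rose in both, for example Ncl (1.99 ± 0.053 and 1.97 ± 0.053) and Nop16 (2.57 ± 0.075 and 2.64 ± 0.076). Of 25 p53 targets 18 rose and 5 fell in WT, and 17 rose and 7 fell in CKO. The most significant p53 targets were Gtse1 (6.62 ± 0.131 in WT), a gene of the G2 phase, and Btg2 (-2.99 ± 0.055 in WT), an inhibitor of cell division, which fell. Only 9 of the 22 replication-dependent histone genes listed were tested, of which 5 rose and 1 fell in WT, and 4 rose and 3 fell in CKO. Their summed level fell from 140 ± 18.2 CPM to 14.1 ± 1.32 CPM in WT and from 160.5 ± 8.53 CPM to 11.7 ± 2.16 CPM in CKO (SD, n = 3), most of it Hist1h1c (-4.74 ± 0.137 and -5.10 ± 0.144). The sum therefore does not stand for histone genes as a group. Among 26 apoptosis regulators 14 rose and 7 fell in WT and 15 rose and 8 fell in CKO, with Bcl2l1, which protects cells from death, at 4.24 ± 0.101 and 3.94 ± 0.098. The camera call of the apoptosis list in CKO was lost, with adjusted p = 0.105 with an estimated correlation, and that in WT was kept.

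Metabolic genes were read next. All 20 glycolysis genes rose in both genotypes, with medians of 2.79 in WT and 2.33 in CKO, including Pgk1 (4.02 ± 0.072 and 3.88 ± 0.072), Ldha (3.40 ± 0.074 and 3.32 ± 0.074) and Tpi1 (5.41 ± 0.098 and 4.88 ± 0.097). Of 24 cholesterol synthesis genes 22 rose and 1 fell in both, with Idi1 at 3.91 ± 0.087 and 4.04 ± 0.086 and Sqle at 3.01 ± 0.072 and 2.83 ± 0.071. Of 24 HIF-1 targets 21 rose and 3 fell in WT and 21 rose and 1 fell in CKO, with adjusted p = 0.0754 in WT and 0.103 in CKO with an estimated correlation. Ak4, a mitochondrial adenylate kinase, led them (7.22 ± 0.221 and 7.92 ± 0.287). Of 46 nuclear genes of oxidative phosphorylation 44 rose in WT and 43 in CKO, at medians of 0.98 and 0.91 (adjusted p = 0.274 and 0.316 with an estimated correlation), and of 20 TCA cycle genes 18 and 17 rose (adjusted p = 0.250 in each with an estimated correlation). Of 27 ATF4 targets 23 rose in both, while 1 fell in WT and 3 in CKO (adjusted p = 0.0754 and 0.117 with an estimated correlation). Psat1 and Mthfd2, enzymes of serine and one-carbon metabolism, were at 3.82 ± 0.081 and 3.34 ± 0.076 in WT. Among 20 genes of the unfolded protein response 15 rose in both, while 3 fell in WT and 4 in CKO (adjusted p = 0.448 and 0.531 with an estimated correlation). Dnajb9, a chaperone partner, fell by 4.07 ± 0.095 in WT. Of 21 fatty acid oxidation genes 16 rose and 3 fell in WT (adjusted p = 0.379 with an estimated correlation), and 13 rose and 3 fell in CKO, where camera did not call the list. Of 21 sirtuin, biogenesis and antioxidant genes 14 rose in both, while 3 fell in WT and 4 in CKO, and camera did not call the list. Of 13 mitochondrially encoded mRNAs 2 fell in WT and 1 rose in CKO. These were mt-Co1 and mt-Atp8 in WT and mt-Nd1 in CKO, none of them past the test adjusted over the list alone. The call of mt-Co1 ended without WT replicate 3 at 0 h (adjusted p = 0.103) or replicate 1 (0.133) or 2 (0.128) at 48 h, and without WT replicate 1 of both times (0.0872). That of mt-Atp8 ended without these (0.189, 0.108, 0.165, 0.115) or WT replicate 1 at 0 h (0.0625). It also ended with DESeq2 (0.0774), no count filter (0.148), thinned counts (0.0798), a replicate block (0.0565) or a block within each genotype (0.0684). That of mt-Nd1 ended without CKO replicate 2 at 48 h (0.0533) and with the stricter filter (0.109).

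Genes of the naive state and of receptor signalling fell. Of 22 naive and quiescence genes 20 fell and 2 rose in WT and 19 fell and 2 rose in CKO, at medians of -2.12 and -2.28. Il7r, the receptor for the survival factor interleukin 7, fell by 3.75 ± 0.074 and 3.79 ± 0.074. Of 30 T-cell receptor signalling components 22 fell and 4 rose in WT and 24 fell and 4 rose in CKO, with Cd8b1, a chain of the CD8 co-receptor, at -1.36 ± 0.070 and -1.62 ± 0.070. Of 34 cytokine and chemokine receptors 23 fell and 9 rose in WT and 22 fell and 7 rose in CKO. Among 20 memory-associated genes 12 fell and 6 rose in WT and 13 fell and 6 rose in CKO (adjusted p = 0.274 and 0.250 with an estimated correlation), with Tcf7, a transcription factor of naive and memory cells, at -2.40 ± 0.077 and -2.62 ± 0.077. Of 26 early activation genes 16 rose and 4 fell in WT and 15 rose and 6 fell in CKO (adjusted p = 0.198 and 0.250 with an estimated correlation), with Tfrc, the transferrin receptor, at 3.32 ± 0.061 and 3.45 ± 0.061. Of 27 cytokines and chemokines 19 rose and 2 fell in WT and 21 rose and 5 fell in CKO (adjusted p = 0.237 and 0.250 with an estimated correlation), and Csf2, which encodes GM-CSF, was at 4.89 ± 0.608 and 7.16 ± 0.820. Of 20 STAT5 targets 16 rose and 2 fell in WT and 15 rose and 2 fell in CKO (adjusted p = 0.0586 and 0.103 with an estimated correlation). The 29 cytotoxic effector genes split evenly, with 13 up and 13 down in WT and 12 and 12 in CKO. Ctsw, which encodes a cathepsin of killer cells, fell by 2.60 ± 0.075 in WT and 2.66 ± 0.075 in CKO. Of 20 inhibitory receptor genes 7 rose and 7 fell in WT and 8 rose and 7 fell in CKO, with Lag3 at 5.64 ± 0.436 and 5.37 ± 0.433. Of 20 SUMO pathway genes 10 rose and 7 fell in both. The SUMO-activating enzyme genes Sae1 (1.64 ± 0.067 and 1.79 ± 0.068) and Uba2 (1.29 ± 0.059 and 1.35 ± 0.059) rose, and the SUMO protease gene Senp7 fell by 1.36 ± 0.070 and 1.42 ± 0.069. Of 31 type I interferon genes 22 rose and 4 fell in WT and 17 rose and 5 fell in CKO, without a camera call. Of 26 interferon gamma and MHC class I genes 18 rose and 5 fell in WT (adjusted p = 0.531 with an estimated correlation), and 16 rose and 5 fell in CKO without a camera call. Gbp5, an interferon-induced GTPase, was at 4.26 ± 0.085 and 3.98 ± 0.084.

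Markers of other cell types were followed beside these groups. All 20 B-cell genes fell in WT and 18 in CKO (adjusted p = 0.459 and 0.578 with an estimated correlation), and their summed level went from 2573 ± 990 CPM to 469 ± 83.4 CPM in WT and from 1533 ± 135 CPM to 444.6 ± 20.1 CPM in CKO (SD, n = 3). Of 19 natural killer and innate-like T-cell genes 18 fell and 1 rose in WT and 17 fell and 1 rose in CKO (adjusted p = 0.274 and 0.298 with an estimated correlation), with Klra8 at -4.57 ± 0.260 and -5.14 ± 0.278, while their summed level went from 727.7 ± 19.0 CPM to 745.5 ± 40.6 CPM in WT and from 819.8 ± 65.5 CPM to 613.8 ± 54.5 CPM in CKO. Such a summed level follows the members with the most counts, which need not move as the list does. Of 20 myeloid genes 17 fell and 1 rose in WT and 19 fell and 1 rose in CKO (adjusted p = 0.198 and 0.166 with an estimated correlation). All 9 erythroid and platelet genes tested fell in WT and 8 in CKO (adjusted p = 0.189 and 0.250 with an estimated correlation). The globin gene Hbb-bs was at least 279-fold lower at 48 h in WT and at least 150-fold lower in CKO, and Hba-a1 203-fold (55.9 to 1690) and 200-fold lower (35.4 to 7930). Jchain, which encodes the joining chain of secreted antibody, fell by 7.66 ± 1.98 in WT. All 9 neutrophil genes fell in both, without a camera call. Of 10 CD4 and regulatory T-cell genes 4 rose in both, while 1 fell in WT and 2 in CKO, and their summed level went from 514.9 ± 46.7 CPM to 1065 ± 211 CPM in WT and from 630 ± 36.7 CPM to 984.1 ± 97.2 CPM in CKO. Of 18 dissociation and heat-shock genes 9 fell and 4 rose in WT, and 10 fell and 5 rose in CKO (adjusted p = 0.352 in CKO with an estimated correlation). Of 4 tested sex-linked genes, all on the Y chromosome, 1 rose and 2 fell in both. Of the 35 lists tested, camera called 25 in WT and 24 in CKO, 10 and 9 of them also with an estimated correlation, and fry called 31 and 33. Adjusted over the list alone, the counts of genes were the same as above except for 44 oxidative phosphorylation genes, 24 ATF4 targets, 19 B-cell genes and 9 erythroid genes in CKO, no mitochondrial mRNA in either genotype, and 0 and 1 CD4 T-cell genes lower in WT and CKO. The median, the mean and the direction of the test differed in sign for the cytotoxic, inhibitory receptor and histone lists in both genotypes and for mitochondrial mRNAs in CKO, none of which camera called. In CKO fry called the cytotoxic list (fry adjusted p = 0.0255) and the histone list (fry adjusted p = 0.00112), both directed down.

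**Figure D2:**
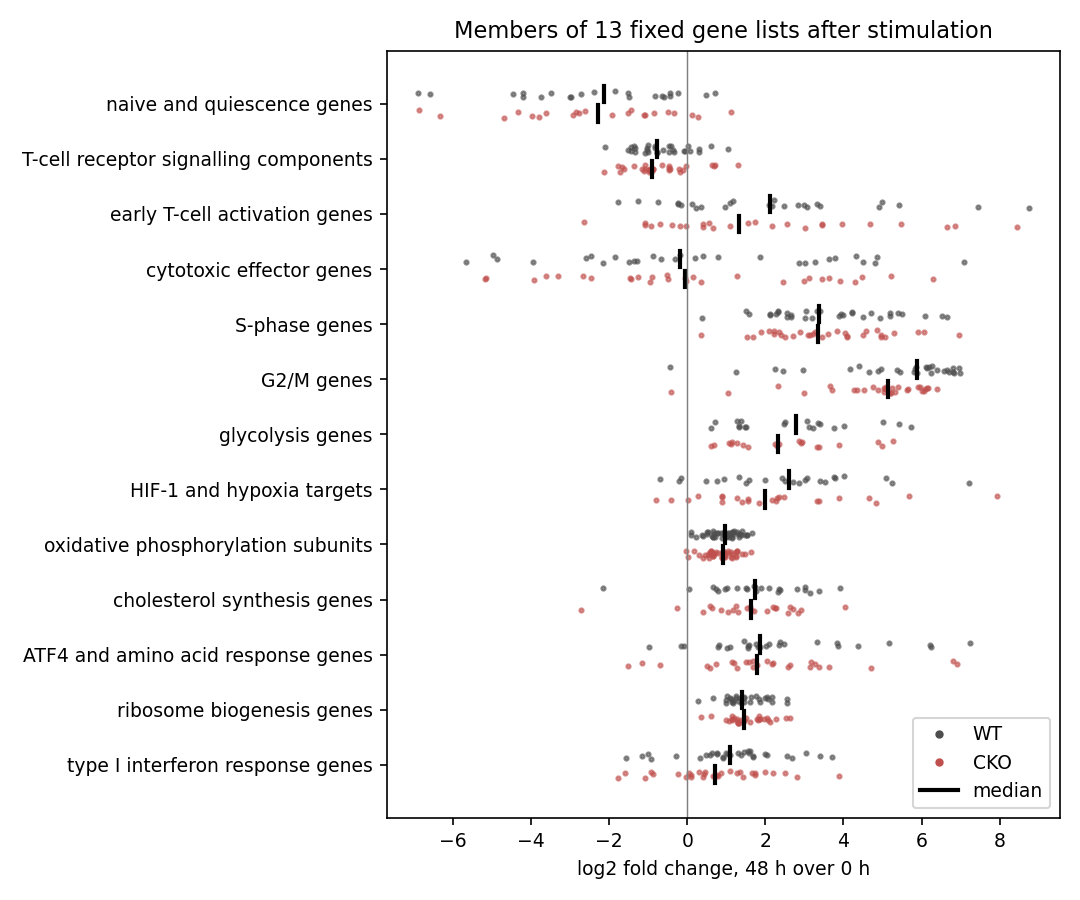
Log2 fold change from 0 h to 48 h (horizontal axis) of the tested members of 13 gene lists. Points are genes, grey for WT and red for CKO, and black bars are medians, which for the G2/M genes lie at 5.88 in WT and 5.14 in CKO and for the naive genes at -2.12 and -2.28.

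The second comparison asked how CKO cells differed from WT cells before stimulation. Ikzf2, which encodes the transcription factor Helios, was higher in CKO by 1.31 ± 0.124 (log2, SE, n = 3 per group, edgeR adjusted p = 5.18e-06), and Pdcd1, which encodes the inhibitory receptor PD-1, by 0.90 ± 0.187 (edgeR adjusted p = 0.00683). Ccr9, the gut-homing receptor, was higher by 1.18 ± 0.109 (edgeR adjusted p = 5.78e-06), and the T-cell receptor gamma constant gene Tcrg-C4 by 1.22 ± 0.235 (edgeR adjusted p = 0.00287). Kif11, a motor protein of the spindle, was higher by 1.06 ± 0.180 (edgeR adjusted p = 0.00224). In all, 654 genes were higher and 538 lower in CKO of 15935 tested, and 218 and 122 of them had a log2 change of at least 1 (edgeR).

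Other genes named for a large change followed. Ddr1, a collagen receptor kinase, was higher by 5.26 ± 0.320, Elavl4, a neuronal RNA-binding protein, by 6.65 ± 0.870, Nrp1, a receptor for semaphorins, by 2.17 ± 0.297, and Rab4a, a GTPase of endosome recycling, by 2.11 ± 0.163. Gprasp2 was higher by 2.71 ± 0.377 and Lrrc6 by 2.52 ± 0.400. The collagen gene Col6a4 had 1 count in the 3 WT libraries together and was 5080-fold higher in CKO (95% counting interval 911 to 201000), and Cpne4 was 920-fold higher (254 to 7600). Mst1 fell by 4.67 ± 0.469, the ribosomal protein gene Rpl29 by 4.02 ± 0.208, F2rl1, a protease-activated receptor, by 3.88 ± 0.421, and Zbtb8a by 3.77 ± 0.336. Tmem108 fell by 2.85 ± 0.236, Tagap1 by 2.53 ± 0.311, Eps8l1 by 2.21 ± 0.278 and the corepressor gene Tle1 by 2.14 ± 0.189. Each of these genes had an edgeR adjusted p of 0.00215 or less and no overlap between the libraries of the genotypes. Col6a4, Cpne4, Mst1, Rpl29 and Tmem108 lie within one stretch of 10 Mb on chromosome 9 (GRCm38). Ccr9 lies in another stretch of that chromosome and Zbtb8a in one of chromosome 4, both taken up in the closing part. With only the 2 groups fitted, the call of Tagap1 ended (adjusted p = 0.0506).

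Among immune genes, 3 of 20 inhibitory receptor genes rose, Ikzf2, Pdcd1 and Cd274, and adjusted over the list alone the count was also 3 (adjusted p = 0.569 with an estimated correlation). Of 26 early activation genes 3 rose, as many as adjusted over the list alone (adjusted p = 0.569 with an estimated correlation), and Slc3a2, a chain of amino acid transporters, was at 0.44 ± 0.075 (edgeR adjusted p = 0.000755). Of 29 cytotoxic genes 4 rose and 1 fell, or 5 and 2 adjusted over the list alone, without a camera call, and Klrd1, an inhibitory receptor chain of killer cells, fell by 0.31 ± 0.063 (edgeR adjusted p = 0.00433). Of 26 interferon gamma and MHC class I genes 7 rose, 13 adjusted over the list alone (adjusted p = 0.511 with an estimated correlation), with H2-K1, which presents peptides, at 0.32 ± 0.057 and the GTPase gene Gbp2 at 1.00 ± 0.144. Of 19 natural killer and innate-like T-cell genes 4 rose, 5 adjusted over the list alone (adjusted p = 0.569 with an estimated correlation). These were Tcrg-C4, Tcrg-C1 (1.17 ± 0.260), the delta constant gene Trdc (1.05 ± 0.200) and the killer receptor gene Klre1 (0.71 ± 0.171). Whether they share reads with similar genes was not measured. Of 10 CD4 and regulatory T-cell genes 2 rose, Ikzf2 and Capg, and 4 adjusted over the list alone (adjusted p = 0.569 with an estimated correlation). Beside these groups, the summed level of the B-cell genes was 2573 ± 990 CPM in WT and 1533 ± 135 CPM in CKO, and that of the natural killer genes 727.7 ± 19.0 CPM and 819.8 ± 65.5 CPM (SD, n = 3). Of 20 B-cell genes only Ighd, an antibody chain gene, passed (-1.02 ± 0.248, edgeR adjusted p = 0.0439), while 13 were lower adjusted over the list alone, at a median of -0.85 (adjusted p = 0.569 with an estimated correlation), or -0.47 without WT replicate 1. The call of Ighd ended without CKO replicate 1 (0.0950), 2 (0.107) or 3 (0.151), with no count filter (0.0760) and with only the 2 groups fitted (0.183). That of Trdc ended without WT replicate 3 (0.0548) and with only the 2 groups (0.0596), and that of Klre1 with only the 2 groups (0.0615) and without WT replicate 2 (0.0510) or 3 (0.0520) or CKO replicate 1 (0.0793) or 3 (0.130). Cd274 lost its call without WT replicate 1 (0.121) or 3 (0.125) or CKO replicate 1 (0.0855), 2 (0.0749) or 3 (0.140) and with no count filter (0.0892), and Capg without WT replicate 3 (0.0649) or CKO replicate 1 (0.0572) or 3 (0.0560).

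Cell-cycle and metabolic genes were read next. Of 30 G2/M genes 8 rose and 2 fell, 12 and 2 adjusted over the list alone, at a median of 0.53 (adjusted p = 0.511 with an estimated correlation). Cdc25c, a phosphatase that starts mitosis, was at 1.76 ± 0.415, while Cks2, a partner of cyclin-dependent kinases, fell by 0.60 ± 0.123. Mki67, a marker of cycling cells, was at 0.97 ± 0.242 (edgeR adjusted p = 0.0462), a call that ended without WT replicate 2 (0.135) or 3 (0.0974) or CKO replicate 1 (0.116) or 3 (0.133), with a replicate block (0.0939), with no count filter (0.0814) and with only the 2 groups fitted (0.132). Among 32 S-phase genes Dtl rose (0.72 ± 0.135) and Cdt1 (-0.32 ± 0.065) and Fen1 (-0.78 ± 0.168) fell, with 1 and 3 adjusted over the list alone, and the call of Fen1 ended with only the 2 groups fitted (0.0809). Of 21 fatty acid oxidation genes 5 rose, 10 with 1 lower adjusted over the list alone (adjusted p = 0.569 with an estimated correlation), for example Acaa2 (0.39 ± 0.072). Of 9 histone genes 1 rose, Hist1h2ae, 3 adjusted over the list alone (adjusted p = 0.511 with an estimated correlation), and of 18 dissociation and heat-shock genes 1 rose, Hsph1 (0.44 ± 0.072; adjusted p = 0.569 for the list with an estimated correlation). Of 9 erythroid genes 1 fell, Slc4a1, 6 adjusted over the list alone (adjusted p = 0.511 with an estimated correlation). In the 6 fits that left out 1 library, the calls of Hist1h2ae (adjusted p up to 0.121) and Slc4a1 (0.138) ended in 5, as did those of Nfkbia of the early activation list (0.138) and Klrg1 (0.190) and Id2 (0.130) of the cytotoxic list. Those of Icos (0.216), Cx3cr1 (0.146) and Hadh (0.0980) ended in 4, that of Decr1 (0.0736) in 3, that of Aurka (0.0558) in 2 and that of Hadha (0.0692) in 1. Of all 87 genes named by the rule and called at 0 h, 49 kept their call in each of these fits. Camera called 11 of 35 lists, all named above, and fry called 5. Without WT replicate 2 the camera calls of the CD4 T-cell (0.120), dissociation (0.0717) and histone lists (0.141) ended, and without WT replicate 3 those of the CD4 T-cell and dissociation lists (0.159 each). The same happened to both without CKO replicate 1 (0.0728 and 0.179), and to the CD4 T-cell and histone lists without CKO replicate 2 (0.0730 and 0.0545). Of 20 SUMO pathway genes 3 rose and 2 fell, 3 and 3 adjusted over the list alone, with a median and a mean of opposite sign. Among them the calls of Pias1 (up to 0.156) and Sae1 (0.185) ended in 4 of the 6 fits and those of Senp7 (0.0799) and Sumo3 (0.103) in 2, while that of Senp1 was kept; without CKO replicate 1 those of Pias1, Sae1 and Senp7 ended together. By edgeR no gene of oxidative phosphorylation (0 of 46), the TCA cycle (0 of 20) or the memory list (0 of 20) passed. Of the set genes, Gzmb (0.70 ± 0.314), Ifng (0.86 ± 0.558), Il2ra (0.42 ± 0.142), Cd44 (-0.62 ± 0.287), Tcf7 (-0.13 ± 0.077), Sirt3 (0.073 ± 0.156) and Hif1a (-0.073 ± 0.097) did not pass. The count of higher genes was 434 without WT replicate 3 and 402 without CKO replicate 3, and the count of lower genes was 347 without WT replicate 2, 316 without CKO replicate 1 and 287 without CKO replicate 3.

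**Figure D3:**
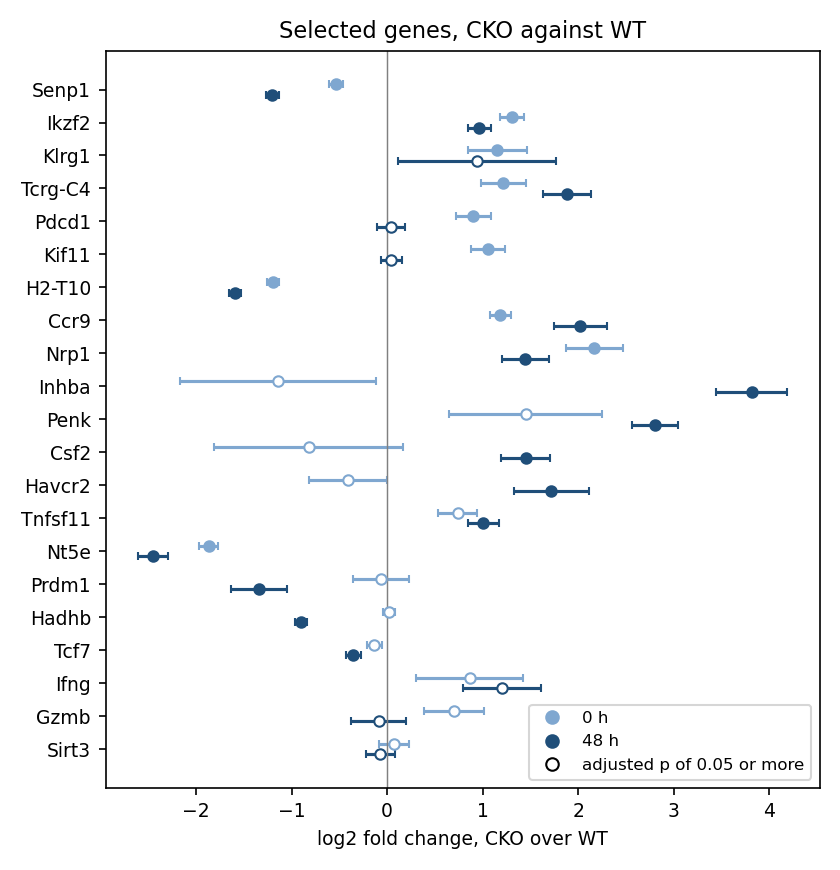
Log2 fold change of CKO over WT (horizontal axis) with its SE for 21 genes at 0 h (light) and 48 h (dark), n = 3 per group. Filled points have an edgeR adjusted p under 0.05. The genes were picked for the plot after their values were seen, and H2-T10 is outside the naming rule. Inhba is higher in CKO at 48 h (3.82) and Nt5e lower (-2.45), and the intervals of Gzmb and Sirt3 are drawn with open points.

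The third comparison asked how the genotypes differed after 48 h of stimulation. Inhba, which encodes a subunit of the growth factor activin, was higher in CKO by 3.82 ± 0.373 (log2, SE, n = 3 per group, edgeR adjusted p = 1.46e-05), and Penk, the precursor of enkephalin peptides, by 2.80 ± 0.236 (edgeR adjusted p = 1.04e-06). The cytokine genes Csf2 (1.45 ± 0.261, edgeR adjusted p = 0.00219) and Tnfsf11, which encodes RANKL (1.00 ± 0.162, edgeR adjusted p = 0.00491), were higher. Nt5e, which encodes CD73, an enzyme that makes adenosine outside cells, fell by 2.45 ± 0.158 (edgeR adjusted p = 1.09e-09), and Hadhb, an enzyme of fatty acid oxidation, by 0.90 ± 0.064 (edgeR adjusted p = 1.62e-08). In all, 375 genes were higher and 349 lower in CKO of 15935 tested, and 160 and 78 of them had a log2 change of at least 1 (edgeR).

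Other large rises were those of the kinase gene Dclk1 (3.50 ± 0.302), Ddr1 (2.33 ± 0.160), Idi2 (2.31 ± 0.275), Crabp2, which binds retinoic acid (2.19 ± 0.326), and Scin, which severs actin (1.89 ± 0.372). Large falls were those of F2rl1 (-4.24 ± 0.682), Rpl29 (-3.96 ± 0.200), Tmem108 (-2.82 ± 0.272), Eps8l1 (-2.72 ± 0.438), Zbtb8a (-2.70 ± 0.261), Pxylp1, a phosphatase of proteoglycan synthesis (-2.31 ± 0.197), and Rps3a1, a ribosomal protein gene (-2.04 ± 0.069). Each had an edgeR adjusted p of 0.0133 or less. Near-identical copies of Rps3a1, outside the naming rule, were counted apart from it, and the level summed over Rps3a1, Rps3a2 and Rps3a3 was 2159 ± 105 CPM in WT and 1592 ± 50.6 CPM in CKO (SD, n = 3). The call of Scin ended without WT replicate 2 (0.0665) or 3 (0.0753) or CKO replicate 2 (0.0539) or 3 (0.0758).

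Of 31 type I interferon genes 3 fell, 8 adjusted over the list alone, at a median of -0.50 (adjusted p = 0.986 with an estimated correlation), or -0.30 without WT replicate 1 and -0.33 without CKO replicate 3. The clearest was Ifit2, an interferon-induced inhibitor of translation (-0.65 ± 0.101, edgeR adjusted p = 0.000575). None of 27 ATF4 targets passed over all genes and 12 were lower adjusted over the list alone, at a median of -0.21 (adjusted p = 0.986 with an estimated correlation), or -0.12 without WT replicate 1. Psph, an enzyme of serine synthesis, had the smallest p among them (-0.33 ± 0.096, edgeR adjusted p = 0.0548). Of 46 oxidative phosphorylation genes 1 fell, Uqcrq, and 0 were lower adjusted over the list alone, at a median of -0.11 (adjusted p = 0.986 with an estimated correlation), or -0.051 without WT replicate 1. Of 19 natural killer and innate-like T-cell genes 3 rose and 2 fell, 5 and 2 adjusted over the list alone (adjusted p = 0.986 with an estimated correlation). The 3 that rose were the receptor genes Tcrg-C4 (1.88 ± 0.249), Tcrg-C1 (1.60 ± 0.320) and Trdc (1.40 ± 0.237), and Il2rb, a chain of the interleukin 2 receptor, fell by 0.36 ± 0.075, a call that ended without CKO replicate 3 (0.0592). Camera called these 4 of 35 lists and fry called none. In the 6 fits that left out 1 library, the calls of Uqcrq (adjusted p up to 0.155) and of the interferon gene Ddx58 (0.255) ended in 5, and that of the interferon gene Isg20 (0.0558) in 1. The oxidative phosphorylation call ended without WT replicate 1 (0.216), and the natural killer call without WT replicate 2 (0.0741) or 3 (0.130). The summed level of B-cell genes was 469 ± 83.4 CPM in WT and 444.6 ± 20.1 CPM in CKO (SD, n = 3), and 0 of 20 were past the edgeR test; camera called that list without WT replicate 1 (0.0335) and without WT replicate 1 of both times (4.76e-04). That of the natural killer genes was 745.5 ± 40.6 CPM in WT and 613.8 ± 54.5 CPM in CKO, against the direction of the list's median (0.38). The mean log2 CPM over the 19 genes ran from 0.1775 to 0.752 in the WT libraries and from 0.5828 to 0.9965 in the CKO libraries. The sum therefore rests on few members and does not measure natural killer cells.

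Other lists had few members past the test. Of 27 cytokines and chemokines 3 rose and 2 fell, 6 and 2 adjusted over the list alone, and Il3 was higher by 1.62 (edgeR adjusted p = 0.00275). Of 34 cytokine receptors 2 rose and 2 fell, 5 and 4 adjusted over the list alone, with Ccr9 (2.02 ± 0.279) and Ifngr2, a chain of the interferon gamma receptor (0.64 ± 0.067), higher. Of 22 naive and quiescence genes 1 rose and 3 fell, 2 and 5 adjusted over the list alone, with Igfbp4 at 0.96 ± 0.094. Tcf7 fell by 0.35 ± 0.078 (edgeR adjusted p = 0.0108). Of 30 T-cell receptor components 2 rose and 3 fell, 4 and 7 adjusted over the list alone, with Cd8a at -0.36 ± 0.056 and Cd6, a surface receptor that tunes signalling, at 0.35 ± 0.064. Of 20 inhibitory receptor genes Ikzf2 (0.96 ± 0.122) and Havcr2, which encodes TIM-3 (1.72 ± 0.395), rose, and of 29 cytotoxic genes Zeb2 rose and Prdm1, a transcription factor of effector cells (-1.34 ± 0.289), fell, as many as adjusted over the list alone. Of 21 fatty acid oxidation genes Hadhb fell and Acadm rose (0.59 ± 0.099), as adjusted over the list alone, with a positive median and a test directed down. Of 20 STAT5 targets 4 fell, 4 adjusted over the list alone, among them Pim2, a survival kinase (-0.41 ± 0.079). By edgeR no G2/M gene (0 of 30), ribosome biogenesis gene (0 of 30) or gene of the sirtuin and antioxidant list (0 of 21) passed. Of the set genes, Gzmb (-0.089 ± 0.286), Ifng (1.20 ± 0.404), Prf1 (-0.15 ± 0.112), Tnf (-0.058 ± 0.267), Il2 (0.74 ± 0.276), Il2ra (-0.17 ± 0.097), Myc (-0.038 ± 0.224), Pdcd1 (0.038 ± 0.146) and Sirt3 (-0.072 ± 0.152) did not pass. The call of Tcf7 ended without CKO replicate 1 (0.0789) or 3 (0.0752) and with only the 2 groups fitted (0.0661), and that of Havcr2 without WT replicate 3 (0.0691) or CKO replicate 1 (0.0815). Prdm1 lost its call without CKO replicate 2 (0.0810) or 3 (0.114) and with only the 2 groups (0.103), and Zeb2 without WT replicate 1 (0.105), 2 (0.0856) or 3 (0.0793) or CKO replicate 1 (0.0969), 2 (0.0546) or 3 (0.0739). In the 6 fits that left out 1 library, the call of Cxcr5 (up to 0.254) ended in 5, that of Cd8b1 (0.145) in 4, those of Dgkz (0.0940), Lta (0.0571) and Socs2 (0.114) in 3 and that of Dapl1 (0.0592) in 2. Of all 65 genes named by the rule and called at 48 h, 36 kept their call in each of these fits. The count of higher genes was 236 without CKO replicate 1 and 204 without CKO replicate 3, and that of lower genes was 223 without WT replicate 3, 183 without CKO replicate 1, 141 without CKO replicate 3 and 653 with no count filter.

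The genotype effects of both times were then set side by side. Genes higher in CKO at both times numbered 134, against 15.4 if the calls were independent, and genes lower at both numbered 117, against 11.8, with 9 and 9 called in opposite directions. The labels do not say whether both times share animals. All 12 libraries correlated best with their own number at the other time of their genotype (0.0424 to 0.162). Differences between the animals other than Senp1 could then recur at both times, so the overlap is not an independent repeat of a Senp1 effect. Ikzf2, Ccr9, Ddr1 and Tcrg-C4 were among the genes higher at both times, and Senp1, Rpl29, F2rl1 and Tmem108 among those lower. Across genes, which are not independent replicates, the effects had a Pearson r of 0.338 and a Spearman rho of 0.223. Over the 10969 genes left by a stricter count filter r was 0.599.

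The fourth comparison asked whether the response to stimulation itself differed between the genotypes. Alcam, an adhesion molecule that binds Cd6, rose more in CKO (5.20 ± 0.151) than in WT (3.40 ± 0.122), a difference of 1.80 ± 0.194 (log2, SE, n = 3 per group, edgeR adjusted p = 3.50e-05). Hadhb was at 0.25 ± 0.063 in WT and -0.67 ± 0.064 in CKO, a difference of -0.92 ± 0.090 (edgeR adjusted p = 2.03e-05). The mitosis genes Psrc1 (-2.01 ± 0.293), Kif18b (-1.83 ± 0.290) and Pimreg (-2.46 ± 0.511) rose less in CKO than in WT (edgeR adjusted p of 0.00399 or less). A smaller rise does not by itself mean a lower level at 48 h. Pdk1, a kinase that holds back the entry of pyruvate into the TCA cycle, differed by -0.57 ± 0.085 (edgeR adjusted p = 0.00113), and Trp53inp1, a p53 target, by -0.68 ± 0.106 (edgeR adjusted p = 0.00152). In all, 97 genes had a more positive and 123 a more negative response in CKO of 15935 tested, with 42 and 40 of them by a log2 difference of at least 1 (edgeR).

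Other genes with a large difference were Ddr1 (-2.93 ± 0.358), Mst1 (3.04 ± 0.591) and Trim30c (1.78 ± 0.349), each with an edgeR adjusted p of 0.0112 or less. Bcl2l11, which encodes the death factor Bim, differed by -0.58 ± 0.109 (edgeR adjusted p = 0.00909), Pim2 by -0.62 ± 0.114 (edgeR adjusted p = 0.00731) and Slc3a2 by -0.55 ± 0.106 (edgeR adjusted p = 0.0102). Of 30 G2/M genes 1 rose more and 1 less in CKO, 2 and 5 adjusted over the list alone, at a median difference of -0.55 (adjusted p = 0.486 with an estimated correlation), or -0.31 without CKO replicate 3 at 0 h. In CKO against WT the median of this list was 0.53 at 0 h and 0.096 at 48 h, where no member passed the edgeR test. By these medians the smaller rise in CKO went with a higher level at 0 h, not with a lower one at 48 h. Of 24 cholesterol synthesis genes 2 rose less in CKO, and 5 adjusted over the list alone (adjusted p = 0.486 with an estimated correlation). The B-cell list had a median difference of 0.93 with 0 of 20 members past the edgeR test (adjusted p = 0.524 with an estimated correlation), or 0.52 without WT replicate 1 at 0 h. Camera called 14 of 35 lists and fry none, and over these 14 the adjusted p ran from 0.431 to 0.808 with an estimated correlation. The call of the oxidative phosphorylation list ended without WT replicate 2 (0.314) or CKO replicate 2 (0.236) at 0 h or WT replicate 1 at 48 h (0.401), and that of the interferon gamma list without WT replicate 3 at 0 h (0.0882). That of the early activation list ended without WT replicate 2 (0.119) or 3 (0.0509) or CKO replicate 1 (0.0556) or 3 (0.0823) at 0 h or CKO replicate 2 at 48 h (0.0879). That of the dissociation list ended without WT replicate 3 (0.164) or CKO replicate 1 (0.134) at 0 h or WT replicate 1 (0.290) or CKO replicate 2 (0.0648) at 48 h. Among set genes the interaction was not past the test for Pdcd1 (-0.87 ± 0.237, edgeR adjusted p = 0.0974), Gzmb (-0.79 ± 0.425) or Il2ra (-0.59 ± 0.172). With no count filter the counts were 223 and 353, and with DESeq2 203 and 218. More positive responses numbered 59 without WT replicate 2 at 0 h, 59 and 61 without WT replicates 2 and 3 at 48 h, 64 and 61 without CKO replicates 1 and 3 at 0 h, and 58 and 43 without CKO replicates 1 and 3 at 48 h, and more negative ones 207 without WT replicate 1 at 48 h, 77 without CKO replicate 3 at 0 h and 72 without CKO replicate 3 at 48 h.

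**Figure D4:**
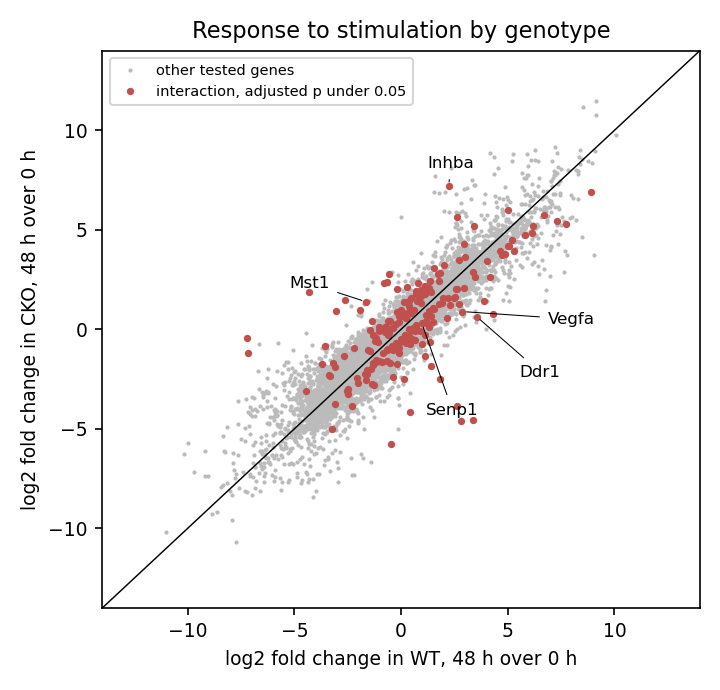
Log2 fold change from 0 h to 48 h in WT (horizontal axis) against that in CKO (vertical axis) for the 15935 genes tested. Red points are the 220 genes whose responses differed (edgeR adjusted p under 0.05), and the diagonal marks equal responses. Inhba lies above the line, and Ddr1, Vegfa and Senp1 lie below it.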

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

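Of the tests in this part, those of the bunching along the chromosomes, of reads shared between genes, of the summed Rps3a copies, of the share of CD8 T cells, of natural killer genes and of a single WT library were chosen only after the result was seen. The genes below are those named by the rule whose response to stimulation differed between the genotypes by the edgeR test of the interaction (adjusted p under 0.05, n = 3 per group). In all, 97 genes responded more positively and 123 more negatively in CKO. Values are differences in log2 change, CKO minus WT.

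The responses of Inhba (4.96), Mst1 (3.04), Gucy1a1 (3.02), H2-DMb1 (1.95), Fscn1 (1.81), Alcam (1.80), Trim30c (1.78), Chst3 (1.52), Perp (1.33), Aurka (0.67), Cd6 (0.40) and Mcl1 (0.37) were more positive in CKO. Those of Ddr1 (-2.93), Pimreg (-2.46), Psrc1 (-2.01), Vegfa (-1.98), Kif18b (-1.83), Fam221a (-1.71), Klra7 (-1.56), Pxylp1 (-1.40), Ddit3 (-1.08), Kif11 (-1.01), Gbp6 (-0.97) and Hadhb (-0.92) were more negative. So were those of Dtl (-0.71), Herpud1 (-0.68), Trp53inp1 (-0.68), Senp1 (-0.67), Pim2 (-0.62), Bcl2l11 (-0.58), Pdk1 (-0.57), Slc3a2 (-0.55), Dhcr7 (-0.50), Cyp51 (-0.47) and Pfkp (-0.43). Of 34 of these genes, Senp1 among them and Pxylp1 not, 15 kept an adjusted p under 0.05 whichever 1 library was left out. Without WT replicate 1 at 0 h the calls of Cd6, Dtl, Fam221a, Gucy1a1, Klra7, Perp and Pfkp ended (adjusted p 0.0511 to 0.0824). Without WT replicate 2 at 0 h those of Aurka, Cd6, Ddit3, Dhcr7, Fam221a, Fscn1, Gucy1a1, Herpud1, Inhba, Kif11, Klra7, Mcl1, Perp and Vegfa ended (0.0600 to 0.121). Without WT replicate 3 at 0 h those of Aurka, Cyp51, Ddit3, Dhcr7, Dtl, Fam221a, Gucy1a1, H2-DMb1, Herpud1, Inhba, Kif11 and Pfkp ended (0.0549 to 0.182). Without WT replicate 1 at 48 h it was Chst3, Inhba and Vegfa (0.0672 to 0.0695). Without WT replicate 2 at 48 h it was Aurka, Cd6, Chst3, Dhcr7, Dtl, Fam221a, Fscn1, Gucy1a1, H2-DMb1, Inhba, Kif11, Klra7, Mcl1 and Vegfa (0.0503 to 0.123). Without WT replicate 3 at 48 h it was Aurka, Chst3, Ddit3, Dhcr7, Dtl, Fam221a, Gucy1a1, H2-DMb1, Kif11, Mcl1, Pfkp and Vegfa (0.0513 to 0.128). Leaving out CKO replicate 1 at 0 h ended Cd6, Ddit3, Fam221a, Gucy1a1, Herpud1, Inhba, Kif11, Klra7, Mcl1, Perp, Pfkp and Vegfa (0.0555 to 0.105). Leaving out CKO replicate 2 at 0 h ended Aurka, Chst3, Dhcr7, Gucy1a1, H2-DMb1 and Inhba (0.0606 to 0.112). Leaving out CKO replicate 3 at 0 h ended Aurka, Cd6, Chst3, Ddit3, Dtl, Fam221a, Fscn1, H2-DMb1, Herpud1, Inhba, Kif11, Klra7, Mcl1, Perp and Pfkp (0.0643 to 0.124). At 48 h, leaving out CKO replicate 1 ended Aurka, Cd6, Chst3, Ddit3, Dtl, Fam221a, Gucy1a1, H2-DMb1, Herpud1, Kif11 and Klra7 (0.0514 to 0.116). At 48 h, leaving out CKO replicate 2 ended Cd6, Chst3, Ddit3, Fam221a, Fscn1, Gucy1a1, H2-DMb1, Kif11, Klra7, Mcl1, Pfkp and Vegfa (0.0530 to 0.102). At 48 h, leaving out CKO replicate 3 ended Aurka, Cd6, Chst3, Ddit3, Dhcr7, Dtl, Fam221a, Gucy1a1, Herpud1, Kif11, Klra7, Mcl1, Perp, Pfkp and Vegfa (0.0508 to 0.134). Without WT replicate 1 of both times, the calls of Gbp6 (0.0756), Inhba (0.118), Klra7 (0.0767) and Vegfa (0.0887) ended. Thinned counts ended Chst3 (0.0755), Fam221a (0.0534), Gucy1a1 (0.0681) and Inhba (0.0501), and the stricter filter Gucy1a1 (0.0517). A replicate block ended Kif11 (0.0535) and Vegfa (0.0512), and a block within each genotype Vegfa (0.140).

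Other splits of the libraries were counted beside the calls. For the interaction, 2 of 100 splits called as many genes as the real one (220), itself included. These splits mix WT with CKO libraries that differ at each time, which widens the spread within groups and can lower the counts, so this test does not exclude chance. The other split called 263 and kept all 3 WT libraries as WT at 0 h and 1 at 48 h, so that the genotypes were largely exchanged at 48 h. The next called 150, and 83 called none. For WT activation (12409 called, highest other split 0), CKO activation (12377, 0), CKO against WT at 0 h (1192, 19) and at 48 h (724, 1), 1 of 10 splits was as large in each, the real one, and 10 splits are too few for a share under 0.05.

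The first pattern is that the 251 genes called in the same direction at both times in CKO against WT were bunched along the chromosomes (GRCm38), for example Tmem108, Cpne4, Col6a4, Rpl29 and Mst1 in a stretch of chromosome 9 and Ddr1, H2-T22 (outside the naming rule) and H2-K1 in one of chromosome 17, though the call of H2-K1 at 48 h ended in 5 of 6 fits that left out 1 library (adjusted p up to 0.0947) and with only the 2 groups fitted (0.0512). A first test, of neighbouring pairs among the 190 protein-coding ones, gave 7 pairs, above the 6 that bound 95% of shuffles (mean 2.77, at most 10) but as many as in an equally large set of activation genes (7), while genes called at 1 time only had 173 pairs against a bound of 135, and the test by stretches of 10 Mb was chosen after it. In that test, run on 170 protein-coding ones (without Senp1, and 1 per name family and stretch), the unevenness was 391 against at most 304.3 in 10000 shuffles and 209.7 in as many activation genes. These genes were thus more bunched than shuffled sets or activation genes. Reads shared between nearby genes could bring this about, so the test cannot decide on Senp1 loss acting on each gene on its own. Among the 113 that share no 50-base word with a transcript of another gene the unevenness was 236.3, reached by 2 of 10000 shuffles (at most 254.8), short of the bound set for this test, so reads shared between paralogs or pseudogenes stay open, and the odds of a call within 10 Mb of Senp1 were 1.12 times those elsewhere (0.227 to 3.37), too wide to decide on DNA around Senp1 itself. Another candidate explanation left open is DNA of another strain in the CKO or the WT mice, for which no strain, read or variant was available here, and an effect of Senp1 loss on whole stretches was not tested. Ccr9, Zbtb8a and Rps3a1, also called at both times, lie in other stretches with many such genes, on chromosomes 9, 4 and 3. The explanations left open hold for them too.

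The second pattern is that Rps3a1 was lower in CKO at both times (-1.86 at 0 h and -2.04 at 48 h) while its pseudogenes Rps3a2 and Rps3a3, outside the naming rule, were higher. Summed over the copies, the level differed by -0.318 at 0 h and -0.439 at 48 h, which argues against a lower amount of Rps3a1 RNA as the whole cause. Of the 50-base words of the Rps3a1 transcript, 61.4% occur in Rps3a2 and 39.9% in Rps3a3. Reads of Rps3a1 may therefore have been counted at another copy in CKO, which a strain variant could bring about, and the remaining fall of the sum stays open.

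The third pattern is that at 0 h B-cell genes were lower in CKO (median -0.85) and natural killer and innate-like T-cell genes higher (median 0.41, or 0.22 and 0.71 without CKO replicate 3 and 2), by camera calls that were lost in both lists (adjusted p = 0.569 with an estimated correlation). Medians of opposite sign cannot decide on a lower share of CD8 T cells in CKO, since that share can be lower while some other cells rise and others fall. Without WT replicate 1 at 0 h the median of B-cell genes was still -0.469 (camera adjusted p = 6.30e-04 with the preset correlation). Their summed level was 3716 CPM in that library, 2002 CPM in each of WT replicates 2 and 3, and 1427 to 1685 CPM in the CKO libraries. By these sums that library held a large part of the difference, while the other WT libraries still stood above CKO. The natural killer genes Ncr1 and, outside the naming rule, Klrb1c, Tyrobp and Fcer1g had a median of 0.262 against 1.17 for Tcrg-C1, Tcrg-C4 and Trdc, which argues against natural killer cells as the source of the receptor transcripts. Of 10 other gamma delta T-cell genes 7 were higher in CKO (median 0.718), and a larger share of gamma delta T cells cannot be told apart from a higher level of these transcripts in the CD8+ cells, since 7 of 10 is fewer than the share set beforehand. How the CD8+ cells were isolated is not given in the sources used here.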

How the results depend on the processing

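The fits without 2 WT libraries and with a replicate block within each genotype were chosen only after the data were seen. No named gene past its test in either fit changed direction in any alternative. Lists were tested again only with median-of-ratios factors, a replicate block, each library left out, 2 WT libraries left out, an estimated correlation and fry. No list past its test in either fit changed direction there. Lists that camera did not call with all 12 libraries did, such as B-cell genes at 48 h (median 0.041, -0.15 without WT replicate 2, and 0.41 without WT replicate 1, where camera called them). So did type I interferon genes at 0 h (-0.070, 0.016 without WT replicate 2, and -0.20 without WT replicate 3, where camera called them). Of the named results, 594 were on the same side of the threshold with DESeq2 (19 gained, 2 lost), 612 with median-of-ratios factors (3 lost), 607 with library totals (8 lost), 581 with no filter (28 gained, 6 lost) 600 after thinning (11 lost, 1 gained), 569 with the stricter filter (6 lost, 2 gained), 480 with only the 2 groups fitted (27 lost, 7 gained) and 586 without 2 WT libraries (17 lost, 12 gained). Camera lost 59 of its list calls with an estimated correlation. Senp1 in CKO was 69.1% to 70.0% of WT at 0 h and 43.5% to 44.0% at 48 h over the scalings. A replicate block gave 705 and 608 genes at 0 h, 455 and 393 at 48 h and 133 and 148 in the interaction; all 12 libraries correlated best with their own number at the other time of their genotype, at 0.0424 to 0.162, a hint from the data and not the design. Without 2 WT libraries 853 and 642 genes were called at 0 h and 478 and 424 at 48 h. With 3 libraries per group, log2 changes of 0.5 were often missed in simulated counts with 200 changed genes, a setting unlike the activation contrasts.

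The following counts of higher and lower genes moved by over 1.5 times, and the cause was not tested unless named. With no filter 653 genes were lower at 48 h, and the interaction gave 223 and 353. A log2 change of at least 1 by construction left 3583 and 3955 in WT activation, 3560 and 3979 in CKO activation, 218 and 122 at 0 h, 160 and 78 at 48 h, and 42 and 40 in the interaction. For the interaction DESeq2 gave 203 and 218, the block within genotype 175 more positive and the fit without 2 WT libraries 227 more negative. The genotype effects at both times had a Pearson r of 0.599 under the stricter filter, against 0.338. Leaving out 1 library gave 402 to 670 higher and 287 to 531 lower at 0 h (lowest without CKO_0h replicate 3), 204 to 384 and 141 to 362 at 48 h, and 43 to 123 and 72 to 207 in the interaction (lowest without CKO_48h replicate 3, highest without WT_48h replicate 1).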

Other observations

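The Y-linked genes were used to check the samples. Ddx3y, an RNA helicase gene of the Y chromosome, fell with stimulation by 1.63 ± 0.062 in WT, and the summed level of the 4 tested sex-linked genes was 667.5 ± 45.7 CPM in WT and 716.2 ± 11.8 CPM in CKO at 0 h, and 340.4 ± 41.1 CPM and 374.1 ± 6.87 CPM at 48 h (SD, n = 3). The summed mitochondrial mRNAs were at 23210 CPM in WT and 21790 CPM in CKO at 0 h and at 21530 CPM and 21990 CPM at 48 h. The squared differences between replicates of a group were 3.96 to 20.9 times those of counting error alone (chi-square per degree of freedom), the most in pairs with WT replicate 1 at 48 h.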
